A study of Caenorhabditis elegans with 10 samples.

How the data were processed

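Whole animals of 5 C. elegans strains were sequenced as RNA-seq libraries, 2 per strain and 10 in all, from total RNA. The deposited values are raw counts per annotated transcript, made by the authors with HTSeq 0.9.1. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.4 and aligned to ce11 with STAR 2.5.4b before counting. The strand setting of the counting step and its annotation release were not given in the sources used here. Each table held 61451 transcripts and 5 summary entries for reads not counted on a transcript, which were left out of the tests. Transcript names were matched to the Ensembl release of the reference annotation: 56781 by identifier and 4581 by sequence name, while 89 names, which held 0.0486% of counts, were kept under their own name. Counts were summed over the transcripts of a gene, which gave 46904 genes.

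A read that fell in more than 1 transcript was not counted on either, whether the transcripts belonged to 1 gene or to several. These ambiguous reads made up 57.7 to 61.8% of aligned reads, and 33.5 to 38.5% were assigned to a transcript. Summed counts therefore cover only the parts of a gene that belong to 1 transcript, and genes with several transcripts are measured in part or not at all. The 5 summary entries and the transcripts together held 33329130 to 40806721 reads per library, of which 49.7 to 49.9% were not aligned. Assigned counts were 6239272 to 7160785 per library. A count of 0 was read as at most 3 counts per library. Intervals on shares are 95% Wilson intervals.

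Groups were the strains as the labels give them. The suppressed strains are called T102I, G265R and unc-16 for short (R9Q_T102I, R9Q_G265R and R9Q_unc-16 in full), and each of them also carries R9Q. All 10 libraries were fitted together in R 4.3.3 with edgeR 4.0.16, with a term per strain and no covariate. Genes were kept by filterByExpr with a minimum count of 10, which left 12267 genes, and libraries were scaled by TMM factors (0.900 to 1.095). Dispersions came from estimateDisp, and each of 10 contrasts was tested by glmQLFit and glmQLFTest with 5 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05, and a gene under it is called. The 4 main contrasts were R9Q against WT and each suppressed strain against R9Q; the other 6 were secondary. Fold changes are log2 values from this fit, and CPM values use the TMM factors. Nothing in the labels says whether the 2 replicates of a strain came from separate cultures, so the p-values measure the spread between these samples. The 3 suppressed strains also lend their larger spread to the comparison of R9Q with WT. In turn, the WT and R9Q libraries lend their smaller spread to every contrast of a suppressed strain. The median biological coefficient of variation was 0.0802 in WT and R9Q and 0.496 in the suppressed strains. P-values of contrasts with a suppressed strain can therefore be too small.

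Gene lists were tested with camera from limma 3.58.1 on log2 CPM with its preset correlation of 0.01, adjusted over the lists of a contrast. The same lists were tested with an estimated correlation and with fry. Of 33 lists fixed in advance, 31 were tested, while 1 had fewer than 3 tested members and 1 served only as a share of counts. Only members that passed the count filter were tested, so numbers of list members refer to these and not to the whole list. No called list of the 4 main contrasts kept its call with an estimated correlation; over all 10 contrasts the pals list in unc-16 against WT was the only one that did. Calls shared between contrasts are set beside the number that independent calls would share, which takes no account of shared libraries. Signs and correlations are set beside 20 simulations of unchanged groups that share the same libraries. The simulated libraries were drawn independently, without a library set or any other difference common to several strains. Named genes followed a fixed rule. It took unc-104 and unc-16, and per main contrast the 8 largest changes in each direction among called genes with a mean count of at least 50, a gene symbol of letters and a number, and both libraries of 1 strain above both of the other. It added up to 3 members of each list with a called member or a called test, the 3 largest changes in each direction per secondary contrast, and the largest R9Q changes called the opposite way in all suppressed strains, of which there were none. Samples, contrasts, tests, lists, the naming rule and most alternatives were set before the data were examined.

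The alternatives set in advance were DESeq2 size factors, upper quartile factors, library sizes without mitochondrial and rRNA genes, no count filter, and a stricter filter of at least 5 CPM in at least 4 libraries. Further ones were the DESeq2 1.42.0 Wald test, only the 4 libraries of a contrast, a replicate block, an adjusted p threshold of 0.01 for the overlaps, and each library left out in turn. A library left out leaves a single sample in its strain, which is assumed to vary like the other strains. Alternatives added after seeing the data were a term for the library set, only the 7 libraries with mitochondrial transcripts, counts per transcript and only genes with 1 transcript. The library set splits the libraries at a share of 0.7% of all reads in no annotated feature, which sets apart 1 library of each suppressed strain. With only the 7 libraries, the spread comes from the WT and R9Q pairs alone.

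The procedure was tested on simulated data with known changes between R9Q and WT in 200 of 12267 genes in 5 rounds. Library sizes, mean levels and spread were those fitted over all 10 libraries, with a median biological coefficient of variation of 0.363. edgeR recovered 0.8% of 2-fold, 21.2% of 4-fold, 32.4% of 8-fold and 55.2% of 16-fold changes, and DESeq2 6, 55.6, 64.8 and 76%. False calls had a median of 4 per round with edgeR (at most 8) and 48 with DESeq2 (at most 59). At that spread a low number of edgeR calls says little about changes below 16-fold. The WT and R9Q libraries alone had a smaller spread (0.0802), at which recovery was not simulated. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.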

Results

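Whole animals of 5 C. elegans strains were profiled by RNA-seq with 2 libraries per strain, 10 libraries in all. The strains were wild type (WT), unc-104(R9Q), and 3 suppressed strains that carried R9Q together with the second unc-104 change T102I, the second unc-104 change G265R, or a mutation in unc-16. These double mutants are called T102I, G265R and unc-16 below, and each of them also carried R9Q. UNC-104 is the kinesin motor that carries synaptic vesicle precursors along axons, and UNC-16 is a scaffold protein of JNK signalling that binds kinesin. Between 6239272 and 7160785 reads per library were counted on single transcripts. A count of 0 allowed up to 3 counts per library, or 0.419 to 0.481 CPM (counts scaled to library size), and these floors and the intervals on shares below cover counting error only. Values are given as mean ± SD of the 2 libraries, and fold changes are log2 values of the first strain over the second. Their SEs and intervals were worked back from the test and can be too narrow for genes with few counts.

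The libraries of WT and of R9Q lay close together, and those of each suppressed strain lay far apart. Between the 2 libraries of a strain, 649 of 12267 genes differed by more than 2-fold in WT and 493 in R9Q, against 2552 in T102I, 4337 in G265R and 4667 in unc-16. In 1 library of each suppressed strain (T102I replicate 1, G265R replicate 2 and unc-16 replicate 2) the mitochondrial genome held 0.0238% of assigned counts (95% Wilson interval 0.0226 to 0.025), 0.02% (0.0189 to 0.0211) and 0.0194% (0.0184 to 0.0205). Their partners held 4.95% (4.93 to 4.96), 5.51% (5.49 to 5.53) and 1.58% (1.57 to 1.59), and the WT and R9Q libraries 3.59 to 4.87%. The same 3 libraries had 14914 to 16449 genes with a count, against 17139 to 18335 in the other 7. The median biological coefficient of variation over genes was 0.363 across the 10 libraries, 0.0802 in WT and R9Q alone and 0.496 in the 3 suppressed strains.

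**Figure D1:**
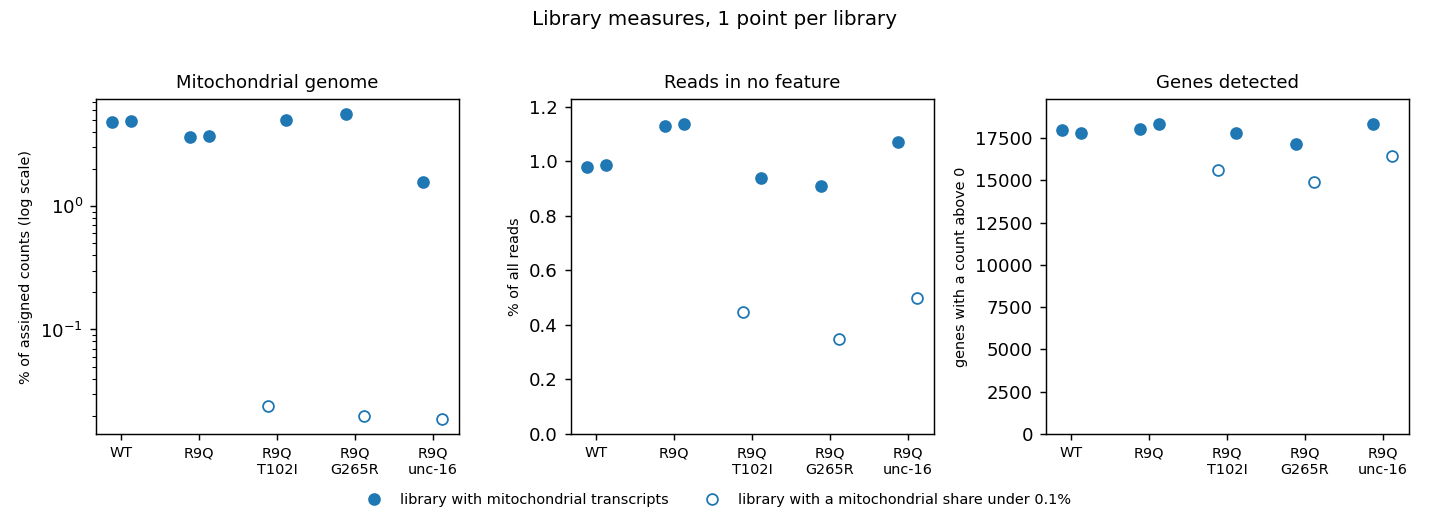
Library measures by strain, 1 point per library: percent of assigned counts on the mitochondrial genome (log axis), percent of all reads in no annotated feature, and number of genes with a count. Open points mark the 3 libraries with mitochondrial shares of 0.0194 to 0.0238%; the filled points of the other 7 lie between 1.58 and 5.51%.

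The purpose given for the libraries was to compare unc-104 mRNA between the strains. No read was counted on unc-104 (WBGene00006831; chromosome II, 6994987 to 7010625, ce11) in any of the 10 libraries, for any of its 4 transcripts, so no fold change can be given for this gene. The counts were made per transcript, and a read that fell in more than 1 transcript was left uncounted. The reference annotation holds 3 of the 4 unc-104 transcripts, and these had 0, 3 and 205 exon bases outside the other 2. The exons of the fourth were not compared, which can only lower these numbers, so the 0 counts do not measure the level of unc-104 mRNA. Among protein-coding genes, 2330 of 6361 with more than 1 transcript had 0 counts in all libraries, against 785 of 13541 with 1 transcript. unc-16 (WBGene00006755; chromosome III, 9546258 to 9557450, ce11) was read on 2 of its 20 transcripts, with 0 to 41 counts per library on the larger. It was at 3.8 ± 3.3 CPM in the unc-16 strain and 4.92 ± 0.32 CPM in R9Q (n = 2; log2 fold change -0.38, SE 1.06, adjusted p = 0.888), a difference within the spread between replicates. This log2 fold change was -1.69 without unc-16 replicate 1 and 0.30 without unc-16 replicate 2, so its sign depended on 1 library. In G265R the unc-16 gene had a log2 fold change of -3.29 against R9Q (adjusted p = 0.511) and -3.38 against WT (adjusted p = 0.341), with 6 and 0 counts in the G265R libraries. It passed the edgeR test in none of the 10 comparisons, and with no count filter or with the 7 libraries with mitochondrial transcripts it passed in G265R against both.

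The comparison of unc-104(R9Q) with WT asks which transcripts differ when the motor carries the R9Q change. Among the genes called, spp-9, cpt-3 and cyp-13B1 were lower in R9Q animals, and col-165 and clec-60 were higher. spp-9, which codes for a saposin-like protein (ce11; WBGene00004994, chromosome X, 11487784 to 11488203), was at 0.413 ± 0.038 CPM in R9Q and 46.4 ± 0.7 CPM in WT (n = 2; log2 fold change -6.75, SE 0.52, adjusted p = 0.00629; 95% interval -7.97 to -5.54), with 3 counts in each R9Q library. cpt-3, a carnitine palmitoyltransferase gene, fell from 56.2 ± 6.4 to 3.49 ± 0.03 CPM (log2 fold change -4.0, SE 0.28, adjusted p = 0.00384). The cytochrome P450 gene cyp-13B1 fell from 211 ± 13 to 14.8 ± 2.2 CPM (log2 fold change -3.83, SE 0.22, adjusted p = 0.0018). The collagen gene col-165 rose from 0.847 ± 0.55 to 23.7 ± 2.1 CPM (log2 fold change 4.78, SE 0.51, adjusted p = 0.025). The C-type lectin gene clec-60 rose from 1.61 ± 0.084 to 34.8 ± 5.5 CPM (log2 fold change 4.42, SE 0.60, adjusted p = 0.0417).

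With edgeR quasi-likelihood and Benjamini-Hochberg adjustment, 38 of 12267 genes differed between R9Q and WT, 12 higher and 26 lower in R9Q. The largest change was that of F56A4.3 (-9.34, adjusted p = 0.0159). It has a sequence name, which the naming rule left out, and is taken up in a later part. The other named genes that rose were the collagen gene dpy-14 (4.10, adjusted p = 0.0417), the C-type lectin gene clec-61 (3.42, adjusted p = 0.0353) and the bZIP transcription factor gene zip-8 (1.27, adjusted p = 0.0417). Those that fell were the C-type lectin gene clec-70 (-4.96, adjusted p = 0.0353) and the enoyl-CoA hydratase gene ech-1.1 (-3.84, adjusted p = 0.0417). The arginine kinase gene argk-1 (-3.57, adjusted p = 0.0417) fell too, as did the acyltransferase gene oac-6 (-2.96, adjusted p = 0.025) and the glucuronosyltransferase gene ugt-37 (-2.93, adjusted p = 0.0417). The xenobiotic list (cytochrome P450, glucuronosyltransferase and glutathione transferase genes) was lower as a set, with 95 of 151 members below 0 and a median of -0.26 (camera adjusted p = 0.000493). The xenobiotic list had adjusted p = 0.431 with an estimated correlation. In it 3 members fell over all genes tested, among them cyp-34A10 (-2.59, adjusted p = 0.0353), and 8 adjusted over the list alone. Fat metabolism genes had a median of -0.41 and were lower as a set (camera adjusted p = 0.0203; adjusted p = 0.306 with an estimated correlation; without WT replicate 2 adjusted p = 0.0538). No member passed over all genes and 2 did adjusted over the list alone. The called genes cpt-3 and ech-1.1 are not members of this list. The desaturase gene fat-7 had a log2 fold change of -3.03 (adjusted p = 0.0646) and fat-1 one of -1.04 (adjusted p = 0.13). The collagen list holds genes with a col symbol only, so the collagen gene dpy-14 is not in it. Among its 98 genes 1 rose and 2 fell over all genes (3 and 9 adjusted over the list alone), with col-144 (-1.60, adjusted p = 0.0417) and col-117 (-1.22) lower. The list as a whole was not called (camera adjusted p = 0.6).

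The FMRFamide-like neuropeptide genes were higher as a set in R9Q, 20 of 22 above 0 with a median of 0.62 (camera adjusted p = 1.84e-05). The FLP neuropeptide list had adjusted p = 0.306 with an estimated correlation. None passed over all genes tested and 3 did adjusted over the list alone. Of these, flp-13 had a log2 fold change of 0.94 (adjusted p = 0.134) and flp-28 one of 1.22 (adjusted p = 0.231). The touch receptor neuron markers were lower as a set, all 5 tested members of the list below 0 with a median of -0.54 (camera adjusted p = 0.00276). The touch neuron list had adjusted p = 0.374 with an estimated correlation. No touch neuron marker passed over all genes and 3 did adjusted over the list alone. mec-7, the beta-tubulin of these neurons, had a log2 fold change of -0.86 (adjusted p = 0.314). Synaptic vesicle genes (median -0.10, camera adjusted p = 0.667), axonal transport genes (0.03, adjusted p = 0.753) and pan-neuronal markers (-0.26, adjusted p = 0.6) were not called. Outside neurons, the pals genes, a family that responds to intracellular infection, were higher as a set with a median of 0.62 (camera adjusted p = 0.000307; adjusted p = 0.17 with an estimated correlation; none called over all genes, 2 adjusted over the list alone), and pals-14 had a log2 fold change of 2.65 (adjusted p = 0.0783). Genes of the vacuolar ATPase had a median of -0.51 (camera adjusted p = 0.011; adjusted p = 0.427 with an estimated correlation) and histone genes one of -0.68 (camera adjusted p = 0.0152). The histone list had adjusted p = 0.777 with an estimated correlation. Summed over all histone genes, the share of assigned counts was not lower in R9Q (0.4056 and 0.4005%) than in WT (0.3963 and 0.3976%). The innate immunity list, which holds spp-9, clec-60 and clec-86, was not called (adjusted p = 0.885), and its median of -0.14 differed in sign from its test, which pointed up.

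The number of genes called between R9Q and WT was 4158 with the 4 WT and R9Q libraries alone, 225 with a term for the library set, 252 with DESeq2 and 3 with a replicate block. It was 3 and 1 without WT replicates 1 and 2, 0 without either R9Q replicate, 5 and 4 without T102I replicates 1 and 2, and 95 and 97 without unc-16 replicates 1 and 2.

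**Figure D2:**
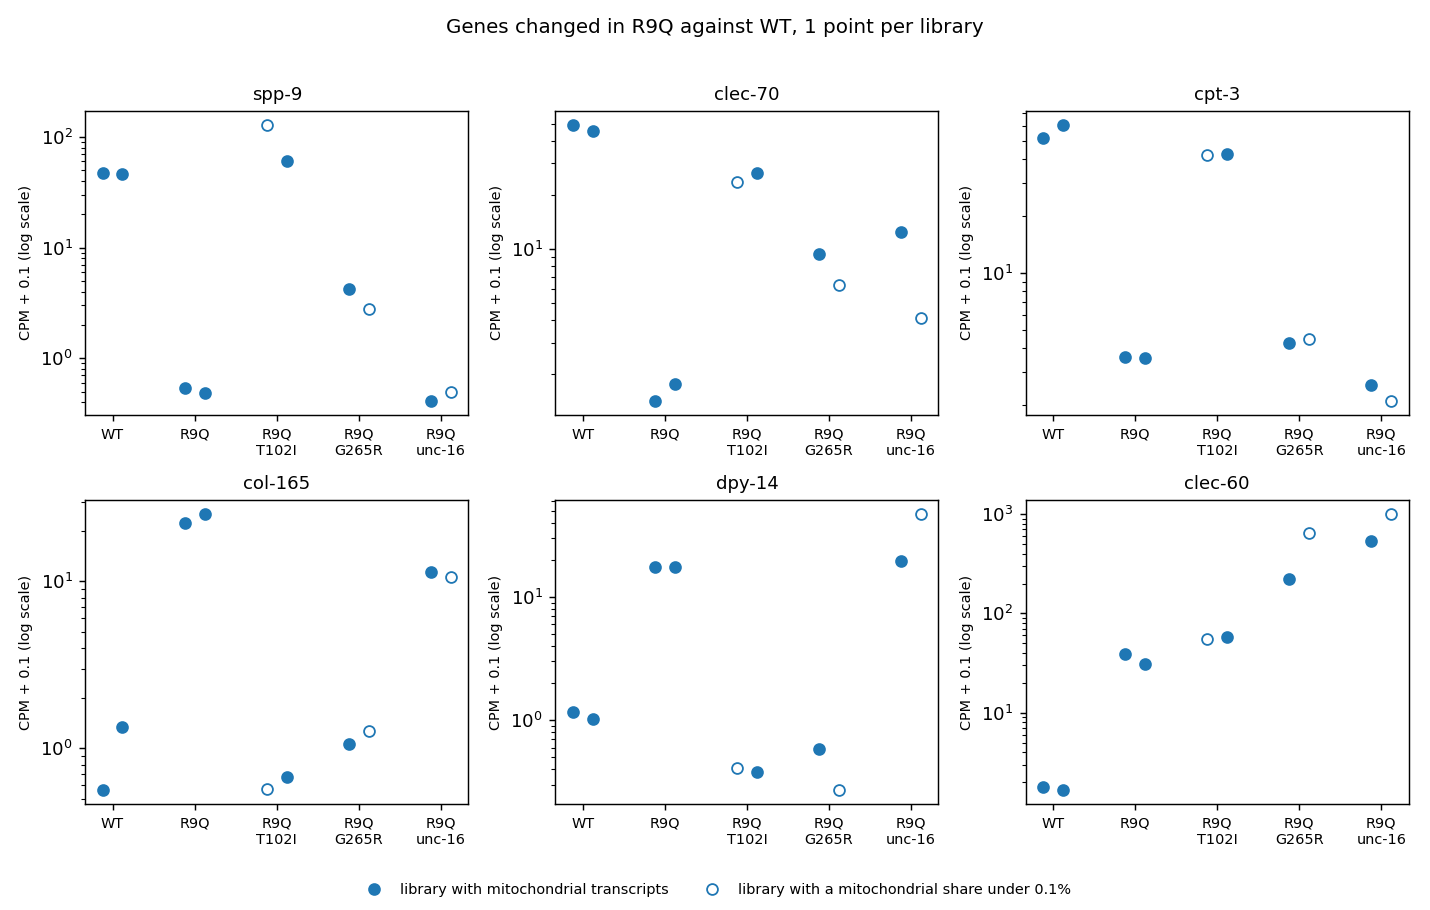
CPM plus 0.1 on a log axis for spp-9, clec-70, cpt-3, col-165, dpy-14 and clec-60, 1 point per library and 2 per strain; open points mark the 3 libraries with mitochondrial shares under 0.1%. spp-9 was at 46.4 ± 0.7 CPM in WT, 0.413 ± 0.038 in R9Q and 94.8 ± 48 in T102I (mean ± SD).

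The comparison of R9Q with T102I against R9Q asks what the second change in the motor alters. Of the 38 genes called between R9Q and WT, 23 were called the opposite way in the T102I double mutant. Both T102I libraries also stood apart in molting genes, with medians of 92.3 and 75.3 CPM against 1.21 to 2.05 CPM in WT and R9Q. The phase of the molting cycle at harvest thus cannot be separated from the second change in this comparison. spp-9 rose from 0.413 ± 0.038 to 94.8 ± 48 CPM (n = 2; log2 fold change 7.78, SE 0.54, adjusted p = 0.00401; 95% interval 6.54 to 9.03). cyp-13B1 rose to 179 ± 21 CPM (log2 fold change 3.60, SE 0.22, adjusted p = 0.00268) and cpt-3 to 42.2 ± 0.65 CPM (log2 fold change 3.59, SE 0.27, adjusted p = 0.00516). dpy-14 fell to 0.299 ± 0.022 CPM, 2 counts in each library (log2 fold change -5.78, SE 0.64, adjusted p = 0.0152; 95% interval -7.26 to -4.30). col-165 fell to 0.519 ± 0.068 CPM (log2 fold change -5.46, SE 0.53, adjusted p = 0.00942). The desaturase gene fat-7 rose and was at 47.3 ± 0.87 CPM against 2.6 ± 0.15 in R9Q (log2 fold change 4.18, SE 0.50, adjusted p = 0.0183).

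With edgeR quasi-likelihood and Benjamini-Hochberg adjustment, 69 of 12267 genes differed between T102I and R9Q, 46 higher and 23 lower in T102I. Named genes that rose included the F-box gene fbxa-6 (4.88, adjusted p = 0.0474), the fatty acid and retinol binding protein gene far-3 (4.48, adjusted p = 0.00942), the glutathione transferase gene gsto-1 (3.98, adjusted p = 0.0265) and clec-70 (4.05, adjusted p = 0.0299). Named genes that fell included clec-68 (-4.95, adjusted p = 0.0275), tag-293 (-4.34, adjusted p = 0.00951) and the peroxidase gene skpo-1 (-4.05, adjusted p = 0.0363). The calexcitin gene cex-1 (-3.45, adjusted p = 0.0226) fell too, as did the glutathione transferase genes gst-12 (-3.15, adjusted p = 0.016), gst-20 (-2.87, adjusted p = 0.0477) and gst-14 (-2.80, adjusted p = 0.0152). The fat metabolism list was higher as a set with a median of 0.62 (camera adjusted p = 0.000514). The fat metabolism list had adjusted p = 0.236 with an estimated correlation. In it 3 genes rose over all genes tested and 4 adjusted over the list alone. Beside fat-7 the 3 were the desaturase gene fat-1 (2.25, adjusted p = 0.00942) and the acyl-CoA synthetase gene acs-2 (2.87, adjusted p = 0.0291). The xenobiotic list went both ways, with 4 members higher and 5 lower over all genes (18 and 15 adjusted over the list alone), and was not called (camera adjusted p = 0.061). Touch neuron markers were higher as a set, 4 of 5 above 0 with a median of 0.65 (camera adjusted p = 0.0105). The touch neuron list had adjusted p = 0.577 with an estimated correlation. None passed over all genes tested and 4 did adjusted over the list alone, and without R9Q replicate 2 the list gave adjusted p = 0.055. The neuropeptide list had a median of -0.24 (camera adjusted p = 0.039; adjusted p = 0.655 with an estimated correlation), and its adjusted p rose to as much as 0.313 without WT replicate 1 or 2, R9Q replicate 1 or 2 or T102I replicate 2.

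The 17 molting genes had a median log2 fold change of 5.35 against R9Q, 16 of them above 0 (camera adjusted p = 8.29e-06). The molting list had adjusted p = 0.655 with an estimated correlation. noah-2, which codes for a protein of the epidermal extracellular matrix, was at 206 ± 5.8 CPM against 2.25 ± 0.28 in R9Q (log2 fold change 6.50, SE 1.90, adjusted p = 0.248). The same genes lay at a median of 92.3 and 75.3 CPM in T102I, 2.08 and 71.5 CPM in the G265R libraries and 6.74 and 318 CPM in the unc-16 libraries. Collagen genes were higher as a set (median 0.68, camera adjusted p = 0.00394, adjusted p = 0.733 with an estimated correlation). In this list, which leaves out the called collagen gene dpy-14, 4 were higher and 1 lower over all genes and 5 and 3 adjusted over the list alone. Those named were col-144 (1.59, adjusted p = 0.0285), col-117 (1.53, adjusted p = 0.0183) and col-165. The epidermal antimicrobial peptide genes were lower as a set (median -2.32; camera adjusted p = 0.000412; adjusted p = 0.733 with an estimated correlation), 2 of them adjusted over the list alone and none over all genes, and cnc-11 had a log2 fold change of -4.04 (adjusted p = 0.116). Mitochondrial genome transcripts had a median of -0.57 (camera adjusted p = 0.00992). The mitochondrial genome list had adjusted p = 0.733 with an estimated correlation. T102I replicate 1 was the library with a mitochondrial share of 0.0238%; without it the mitochondrial list gave adjusted p = 0.637 and the collagen list 0.314, and without T102I replicate 2 the antimicrobial list gave 0.0754. With a term for the library set the collagen list gave adjusted p = 0.524 and the mitochondrial list, now in the upward direction, 0.784.

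The T102I count was 493 with a term for the library set, 455 with DESeq2, 820 with the 4 libraries of the comparison alone and 24 with a replicate block. It was 7 without either WT replicate, 0 without either R9Q replicate, 2 and 4 without T102I replicates 1 and 2 and 258 and 266 without unc-16 replicates 1 and 2; without a G265R replicate it was also more than 1.5 times as high.

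The comparison of R9Q with G265R against R9Q asks the same of the other second change. No single gene passed the test in G265R animals, whose 2 libraries differed by more than 2-fold in 35.4% of genes, but several of the genes above lay in the same direction as in T102I. Both contrasts use the same 2 R9Q libraries, so a common direction is not independent evidence for a shared effect. dpy-14 was at 0.323 ± 0.22 CPM in G265R and 17.4 ± 0.045 CPM in R9Q (n = 2; log2 fold change -5.66, SE 0.64, adjusted p = 0.0957), with 3 counts and 1 count in the G265R libraries. col-165 was at 1.07 ± 0.15 CPM (log2 fold change -4.46, SE 0.50, adjusted p = 0.0957), and the F-box gene fbxa-6 at 38.2 ± 31 against 1.99 ± 0.086 CPM (log2 fold change 4.25, SE 0.75, adjusted p = 0.192). Innate immunity genes were higher as a set, 13 of 15 above 0 with a median of 1.38 (camera adjusted p = 9.95e-05). The innate immunity list had adjusted p = 0.503 with an estimated correlation.

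With edgeR quasi-likelihood and Benjamini-Hochberg adjustment, 0 of 12267 genes differed between G265R and R9Q, with 1069 at an unadjusted p under 0.05; DESeq2 called 229 genes. With a term for the library set, chosen after the data were seen, 126 genes were called by edgeR. The largest of these in each direction among the named genes were fbxa-6 (4.60, adjusted p = 0.0161), clec-60 (3.10, 0.0223) and far-3 (2.86, 0.0161), all higher. Lower were dpy-14 (-6.04, 0.0135), col-165 (-4.44, 0.0153) and the neuropeptide-like antimicrobial gene nlp-28 (-4.29, 0.0135). In the innate immunity list 6 members were higher adjusted over the list alone and none over all genes tested. clec-60 had a log2 fold change of 3.64 (adjusted p = 0.132), spp-9 one of 3.0 (adjusted p = 0.182) and clec-4 one of 2.84 (adjusted p = 0.203). Vacuolar ATPase genes were higher as a set (median 0.40; camera adjusted p = 0.0126; adjusted p = 0.627 with an estimated correlation), 1 of them adjusted over the list alone and none over all genes. vha-12 had a log2 fold change of 1.18 (adjusted p = 0.344). This list gave an adjusted p of up to 0.0653 without G265R replicate 1 or 2.

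Molting genes had a median of 4.31 in G265R against R9Q (camera adjusted p = 0.0354). The list had adjusted p = 0.758 with an estimated correlation, and without G265R replicate 2 it turned downward with an adjusted p of 0.91. It was also downward in the 7 libraries with mitochondrial transcripts (adjusted p = 0.736). The epidermal antimicrobial peptide genes had a median of -1.44 (camera adjusted p = 0.00219; adjusted p = 0.758 with an estimated correlation), 1 of them adjusted over the list alone and none over all genes. Without G265R replicate 1 the list gave adjusted p = 0.508. The mitochondrial genome list had a median of -0.29 (camera adjusted p = 0.0126; adjusted p = 0.758 with an estimated correlation) and gave adjusted p = 0.91 without G265R replicate 2, the library with a mitochondrial share of 0.02%. With a term for the library set the molting list gave adjusted p = 0.581 and the mitochondrial list, now in the upward direction, 0.687. For the mitochondrial genome list, R9Q_G265R against R9Q, the 7 libraries gave a call in the upward direction (adjusted p = 0.00740).

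The G265R count of 0 rose to 9 and 13 without unc-16 replicates 1 and 2 and stayed at 0 without any other single library.

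The comparison of R9Q with unc-16 against R9Q asks what loss or change of the scaffold gene alters in the R9Q animals. Among the genes called, hsp-70 and clec-60 were higher and gst-4 was lower in the unc-16 double mutant. hsp-70, a heat-induced chaperone gene (ce11; WBGene00002026, chromosome I, 9320325 to 9322519), was at 69 ± 38 CPM in unc-16 and 1.45 ± 0.23 CPM in R9Q (n = 2; log2 fold change 5.56, SE 0.64, adjusted p = 0.0249). The C-type lectin gene clec-60, already higher in R9Q than in WT, rose further to 769 ± 327 CPM (log2 fold change 4.47, SE 0.55, adjusted p = 0.0297). gst-4, a glutathione transferase gene of the oxidative stress response, fell from 572 ± 1.6 to 29.6 ± 5.1 CPM (log2 fold change -4.27, SE 0.47, adjusted p = 0.0248). FMRFamide-like neuropeptide genes were lower as a set, 21 of 22 below 0 with a median of -0.88 (camera adjusted p = 2.19e-06). The FLP neuropeptide list had adjusted p = 0.287 with an estimated correlation.

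With edgeR quasi-likelihood and Benjamini-Hochberg adjustment, 82 of 12267 genes differed between the unc-16 strain and R9Q, 50 higher and 32 lower. Other named genes that rose were the F-box gene fbxa-163 (5.05, adjusted p = 0.0248), abu-11 (3.93, adjusted p = 0.0349) and clec-61 (3.86, adjusted p = 0.0144). The enoyl-CoA hydratase gene ech-1.1 (3.65, adjusted p = 0.0386) rose too, as did the beta-tubulin gene tbb-6 (3.14, adjusted p = 0.0308) and the laminin gene lam-3 (3.14, adjusted p = 0.0246). Those that fell were clec-68 (-5.92, adjusted p = 0.0249), gst-25 (-5.0, adjusted p = 0.0392), gst-14 (-3.40, adjusted p = 0.0144) and gst-12 (-3.38, adjusted p = 0.0246), and further gst-16 (-2.67, adjusted p = 0.0346), srlf-37 (-3.19, adjusted p = 0.0144) and cex-1 (-2.85, adjusted p = 0.0392). In the xenobiotic list 1 member rose and 7 fell over all genes tested (11 and 22 adjusted over the list alone), and the list was not called (camera adjusted p = 0.273). All 4 heat shock genes that could be tested were above 0, with a median of 4.33 (camera adjusted p = 0.00107). The other members of the fixed heat shock list were not tested. The heat shock list had adjusted p = 0.338 with an estimated correlation. In this list 1 gene rose over all genes and 3 adjusted over the list alone. The hsp-70 family gene F44E5.4 had a log2 fold change of 4.77 (adjusted p = 0.0644) and hsp-16.41 one of 3.89 (adjusted p = 0.208). The pals genes had a median of 1.05 (camera adjusted p = 1.14e-05; adjusted p = 0.0899 with an estimated correlation), 1 of them higher over all genes, pals-14 (3.05, adjusted p = 0.0331), and 9 adjusted over the list alone. In the innate immunity list 2 members rose over all genes, clec-60 and irg-2 (1.86, adjusted p = 0.0466), and 4 adjusted over the list alone. The list's median of -0.20 differed in sign from its test, which pointed up and was not called (adjusted p = 0.328).

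No neuropeptide gene passed over all genes tested in the unc-16 strain and 10 were lower adjusted over the list alone. flp-9 had a log2 fold change of -1.15 (adjusted p = 0.0746) and flp-21 one of -1.22 (adjusted p = 0.077). Genes of the endoplasmic reticulum unfolded protein response had a median of 0.53 (camera adjusted p = 0.0202; adjusted p = 0.338 with an estimated correlation), and oocyte and eggshell genes one of 0.83 (camera adjusted p = 0.0418). The oocyte and eggshell list had adjusted p = 0.751 with an estimated correlation. Molting genes had a median of 6.46 (camera adjusted p = 3.01e-05; adjusted p = 0.656 with an estimated correlation), 13 of 17 higher adjusted over the list alone and none over all genes, and collagen genes one of 0.83 (camera adjusted p = 0.0102). The collagen list had adjusted p = 0.751 with an estimated correlation. Among the collagens of that list col-10 (1.86, adjusted p = 0.0392) was the 1 that rose over all genes, and 3 did adjusted over the list alone. Epidermal antimicrobial peptide genes had a median of -1.19 (camera adjusted p = 0.00582; adjusted p = 0.751 with an estimated correlation), 3 of them lower adjusted over the list alone and none over all genes. Mitochondrial genome transcripts had a median of -2.45 (camera adjusted p = 0.0102). The mitochondrial genome list had adjusted p = 0.751 with an estimated correlation. Without unc-16 replicate 2, the library with a mitochondrial share of 0.0194%, the molting, collagen and mitochondrial lists gave adjusted p = 0.117, 0.956 and 0.444. Without unc-16 replicate 1 the unfolded protein response and antimicrobial lists gave 0.201 and 0.591, and the oocyte list gave up to 0.711 without that library or R9Q replicate 2. With a term for the library set the collagen list gave adjusted p = 0.69 and the oocyte list 0.356.

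The unc-16 count was 1531 with a term for the library set, 1129 with DESeq2, 18 with a replicate block and 0 with the 4 libraries of the comparison alone. It was 0 without any 1 of the WT or R9Q libraries, 12 without either T102I replicate, 256 and 269 without G265R replicates 1 and 2, and 472 and 681 without unc-16 replicates 1 and 2. Of the genes called, 61.0% were higher in the reported fit and 74.8% without unc-16 replicate 1, but the lower ones led without unc-16 replicate 2 (313 higher, 368 lower) and with the library set term (718 higher, 813 lower).

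**Figure D3:**
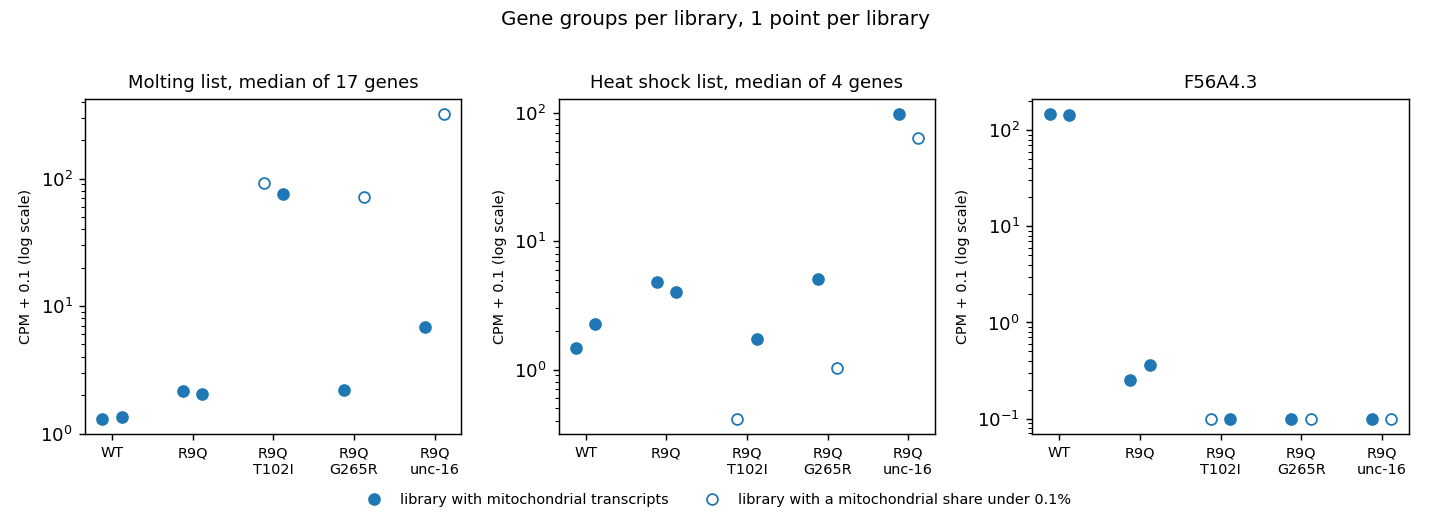
CPM plus 0.1 on a log axis, 1 point per library and 2 per strain, for the median of 17 molting genes, the median of 4 heat shock genes and the gene F56A4.3; open points mark the 3 libraries with mitochondrial shares under 0.1%. Heat shock genes lay at 97.4 and 63.7 CPM in the unc-16 libraries and at 0.315 to 4.95 CPM in the other 8.

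Set against WT, the suppressed strains kept high levels of 2 neighbouring C-type lectin genes. clec-60 was at 1.61 ± 0.084 CPM in WT (n = 2) and 56.5 ± 2.4 CPM in T102I (log2 fold change 5.12, SE 0.61, adjusted p = 0.0432). Its levels were 434 ± 299 in G265R (log2 fold change 8.06, SE 0.68, adjusted p = 0.00678) and 769 ± 327 in unc-16 (log2 fold change 8.88, SE 0.70, adjusted p = 0.00242). clec-61 was higher as well, by log2 fold changes of 5.33, 6.23 and 7.27. Every mutant strain carried R9Q, so the rise of both genes over WT was not separated from other differences that the mutant strains may share. spp-9 stayed below WT in G265R (-3.75, adjusted p = 0.0172) and in unc-16 (-6.95, adjusted p = 0.00242). By edgeR quasi-likelihood, 12 genes differed from WT in T102I (4 higher, 8 lower), 57 in G265R (24 higher, 33 lower) and 547 in unc-16 (278 higher, 269 lower). The other named genes were far-3 (4.06, adjusted p = 0.0284), tag-293 (-4.18, adjusted p = 0.0292), the claudin-like gene clc-19 (-2.79, adjusted p = 0.0432) and the cysteine protease gene cpr-3 (-1.98, adjusted p = 0.036) in T102I. In G265R they were pals-14 (4.48, adjusted p = 0.0127), kreg-1 (-5.17, adjusted p = 0.0109) and the potassium channel gene twk-45 (-4.0, adjusted p = 0.022), and in unc-16 idpc-1 (7.16, adjusted p = 0.0227), the sodium-proton exchanger gene nhx-6 (-8.16, adjusted p = 0.0206), with 1 count in each unc-16 library, and clec-68 (-5.68, adjusted p = 0.00898). With DESeq2 size factors 61.5% of the genes called between unc-16 and WT were higher, against 50.8% with TMM. With 1 library left out the T102I count was 0 without any WT, R9Q or T102I library and 97 without unc-16 replicate 2, and it was higher still without unc-16 replicate 1. The G265R count was 0 without either WT replicate, 8 without either R9Q replicate, 21 and 26 without T102I replicates 1 and 2, 18 without G265R replicate 1, and 140 and 149 without unc-16 replicates 1 and 2. The unc-16 count was 7 and 9 without WT replicates 1 and 2, 82 without either R9Q replicate, and 193 and 212 without T102I replicates 1 and 2. It was 925 and 889 without G265R replicates 1 and 2, and 856 and 1448 without unc-16 replicates 1 and 2. The share of called genes that were higher was 33.3, 42.1 and 50.8% in T102I, G265R and unc-16. It was 52.6, 53.7 and 44.3% without unc-16 replicate 2, 61.1% in G265R without G265R replicate 1, and 58.3 and 62.5% in T102I and G265R with DESeq2.

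The contrasts between suppressed strains test whether their changes against R9Q differ. T102I and G265R differed in 12 genes (6 higher and 6 lower in T102I) by edgeR quasi-likelihood, among them spp-9 (4.79, adjusted p = 0.0182), cpt-3 (3.31, adjusted p = 0.0132), cest-2.1 (3.03, adjusted p = 0.0306) and tag-293 (-4.96, adjusted p = 0.0166). unc-16 and T102I differed in 96 genes (54 higher and 42 lower in unc-16), with dpy-14 (6.71, adjusted p = 0.00863), fbxa-163 (6.68, adjusted p = 0.00863) and hsp-70 (6.37, adjusted p = 0.0132) higher and spp-9 (-7.98, adjusted p = 0.00188), cpt-3 (-4.24, adjusted p = 0.00188) and nspg-7.2 (-4.07, adjusted p = 0.00153) lower. unc-16 and G265R differed in 11 genes (7 higher and 4 lower), with dpy-14 (6.59, adjusted p = 0.0241), tbb-6 (4.11, adjusted p = 0.0241) and abu-10 (3.58, adjusted p = 0.0408) higher and clec-143 (-2.55, adjusted p = 0.0408) and nspg-7.2 (-2.01, adjusted p = 0.0407) lower. These counts ranged from 0 to 70, 5 to 797 and 0 to 375 when 1 library was left out, the highest each time without unc-16 replicate 2. For T102I and G265R the count was 0 without a WT or R9Q library or T102I replicate 1, 1 without T102I replicate 2 and 61 without unc-16 replicate 1. For unc-16 and T102I it was 15 without either WT replicate, 11 without either R9Q replicate, 6 and 5 without T102I replicates 1 and 2, and 190 and 192 without G265R replicates 1 and 2. For unc-16 and G265R it was 0 without any WT, R9Q or T102I library, 7 and 22 without G265R replicates 1 and 2, and 2 without unc-16 replicate 1. The share of called genes higher in unc-16 was 56.2% against T102I and 63.6% against G265R in the reported fit, and 40.2 and 34.9% without unc-16 replicate 2. Against T102I, 2 of 6 and 1 of 5 called genes were higher without T102I replicates 1 and 2, and 94 of 192 without G265R replicate 2. Against G265R, 2 of 7 and 3 of 22 were higher without G265R replicates 1 and 2.

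Of the 38 genes called between R9Q and WT, 23 were called the opposite way in T102I against R9Q: 19 lower in R9Q and higher in T102I, and 4 the reverse. Independent calls would have shared 0.0975 and 0.0225 genes, a number that takes no account of the R9Q libraries in both contrasts. spp-9, cpt-3, cyp-13B1, clec-70, ugt-37, col-165 and dpy-14 were among the 23, and 3 of the 38 were still called against WT in T102I. A difference in molting phase between T102I and the R9Q and WT animals was not separated from this count. In G265R 0 of the 38 were called the opposite way, where edgeR called 0 genes in all (1069 at an unadjusted p under 0.05) and DESeq2 gave 40 such genes of its own 252, and 15 of the 38 were still called against WT. In unc-16 1 of the 38, ech-1.1, was called the opposite way and 2, clec-60 and clec-61, were called further the same way, with 32 still called against WT. By sign alone 35, 30 and 21 of the 38 lay opposite in T102I, G265R and unc-16. In 20 simulations of unchanged groups that share the R9Q libraries the numbers were 30.1, 30.9 and 30.1. There the 38 were the genes with the smallest p between R9Q and WT. Such genes are picked for noise in the R9Q and WT libraries, which by itself turns signs opposite. The simulated numbers therefore do not show what the 38 called genes would give without reversal. Across 12267 genes, which are not independent replicates, the fold changes against R9Q correlated with those of R9Q against WT at r = -0.33, -0.21 and -0.08 in T102I, G265R and unc-16, against -0.18, -0.19 and -0.19 simulated. These r values are not like for like, since changes beyond noise widen the fold changes in the data and not in the simulations. The covariance, which is not divided by that width, lay beyond the simulated value by -0.27, -0.14 and -0.05. For unc-16 the 2 measures pointed opposite ways, with a covariance of -0.098 against -0.045 simulated. With a term for the library set the 23, 0 and 1 genes called the opposite way in T102I, G265R and unc-16 became 103, 28 and 53, with 4, 5 and 33 called further the same way. With DESeq2 there were 60 opposite and 28 further the same way in unc-16. With a replicate block the T102I count was 3. The T102I count was 0 without either R9Q replicate, 3 and 1 without the WT replicates, 2 and 3 without the T102I replicates and 59 and 62 without the unc-16 replicates. The G265R count of 0 was 4 and 6 without unc-16 replicates 1 and 2. The unc-16 count of 1 was 7 without either G265R replicate, 24 and 14 without unc-16 replicates 1 and 2, and 0 without any other single library.

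Against R9Q, T102I and unc-16 shared 14 called genes in the same direction, 5 higher and 9 lower, and 1 gene was called in opposite directions. Independent calls would have shared 0.187 and 0.06 genes, without regard to the shared R9Q libraries. The 14 became 263 with a term for the library set, 224 with DESeq2, 4 with a replicate block and 0 at a threshold of 0.01. T102I and G265R shared 0 genes and G265R and unc-16 also 0, which became 80 and 96 with the set term and 120 and 155 with DESeq2. clec-68, cex-1, gst-12 and gst-14 were among those lower in both. Across genes the fold changes correlated at r = 0.71 for T102I and G265R, 0.68 for T102I and unc-16 and 0.68 for G265R and unc-16, against 0.11 in simulations. The covariance beyond the simulated value was 0.75, 1.01 and 0.89. The simulations held only the shared R9Q libraries. In the data each suppressed strain also had 1 library almost without mitochondrial transcripts. Replicate deviations correlated at -0.64, -0.46 and 0.61 for the same 3 pairs of strains. The excess can therefore not be assigned to effects of the suppressors. All 3 contrasts used the same 2 R9Q libraries, which are too few to be split between them. In the 7 libraries with mitochondrial transcripts the correlations were 0.33, 0.35 and 0.29 and the covariances 0.49, 0.67 and 0.51. No simulation was run for those 7 libraries.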

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

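All tests of explanations in this part were chosen after the result was seen; the contrasts between suppressed strains had been planned. Those contrasts test by edgeR whether 2 suppressed strains differ in their change against R9Q. T102I and G265R differed in 12 genes, among them spp-9 with a log2 difference of 4.79. unc-16 and T102I differed in 96 genes, among them dpy-14 at 6.71, and unc-16 and G265R in 11 genes, among them tbb-6 at 4.11. These numbers moved with the libraries used, as given under the processing alternatives. Outside the comparisons, a median of 59.7% of aligned reads per library was ambiguous between transcripts and entered no comparison, which is where reads of unc-104 would fall.

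A group of 3 libraries, 1 of each suppressed strain, had almost no mitochondrial transcripts. Strain genotype is excluded as the cause, since the 2 libraries of a strain differed at least 81.2-fold in mitochondrial share. For genomic DNA in the other 7 libraries, even coverage was set at within 5-fold and uneven at over 10-fold. Counts per kilobase differed 4.65 to 10.3-fold between the 4 mitochondrial protein genes of at least 1000 bases, so these bounds did not decide. Each of these genes had at least 3158 counts in every one of the 7 libraries. DNA alone would cover them evenly, so the values argue against DNA as the only source for these 4 genes. A part from DNA cannot be told apart. A loss of RNA without poly(A) tails from the 3 libraries cannot be told apart from other causes either. Small nuclear and nucleolar RNA fell to a median of 0.629 of the partner's share (0.612 to 0.638), and counts at piRNA loci to 0.0926 to 0.123. Mitochondrial transcripts themselves fell to 0.00362 to 0.0123. Histone mRNAs, which mostly lack poly(A), went the other way. Their share of assigned counts was 0.33% against 0.22% in the partner for T102I, 0.42% against 0.18% for G265R and 0.25% against 0.18% for unc-16. The WT and R9Q libraries, which had mitochondrial transcripts, held 0.396 to 0.406%. That is above T102I replicate 1 and unc-16 replicate 2 and below G265R replicate 2, so across strains the share did not follow the library set. The 2 libraries of G265R and of unc-16 also differed in molting genes. Histone shares therefore do not decide on such a loss, while the small RNA classes go with it. The labels give no library batch, and no biological explanation beyond genotype was tested.

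Molting genes lay far apart between libraries. Strain genotype alone is excluded, since the G265R libraries differed by a median log2 ratio of 4.55 and the unc-16 libraries by 3.64. The library set alone is excluded too, since in T102I the 2 libraries of different sets differed by -0.0476. The phase of the molting cycle at harvest may account for the G265R and unc-16 pairs: collagen genes, which follow that cycle, spread 1.52 and 1.70 times as widely as all genes between these libraries, though the ratio was also 1.33 in WT and 1.25 in R9Q, and 0.475 in T102I. Why both T102I libraries were high was not tested, and strain genotype and the phase at harvest both stay open for it.

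In the interval from 2345676 to 2473414 of chromosome V (ce11), 2 genes had almost no counts in any mutant library. F56A4.3 (V, 2453414 to 2456147) had 962 and 927 counts in WT and 3 over all 8 mutant libraries, and the pseudogene F15E11.10 had 41 and 36 against 0 to 3. Both were chosen after their values were seen. Whether their closeness is due to chance was not tested. A strain variant in the region that the mutant strains share may lie behind it, but this cannot be told apart from other causes with so few genes: 2 of 2 other genes of the interval, near-identical copies of clec-209, were lower in all 8 mutant libraries, against 4 of 25 in the flanks. The fold changes of these genes in R9Q against WT therefore need not come from the R9Q change.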

How the results depend on the processing

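The library set term, the 7 libraries with mitochondrial transcripts, counts per transcript and genes with 1 transcript were tried only after the data were seen; all other alternatives were planned. Counts of called genes are listed in the order R9Q, T102I, G265R and unc-16 for the main contrasts (R9Q against WT, the others against R9Q), then T102I, G265R and unc-16 against WT, then T102I against G265R, unc-16 against T102I and unc-16 against G265R; the reported counts were 38, 69, 0, 82, 12, 57, 547, 12, 96 and 11. DESeq2 size factors, upper quartile factors, library sizes without mitochondrial and rRNA genes and counts per transcript kept all 10 counts within 1.5 times. With no count filter the counts were 322, 795, 460, 1264, 601, 728, 1672, 334, 685 and 628; with the DESeq2 Wald test 252, 455, 229, 1129, 367, 456, 1659, 186, 603 and 328; with the library set term 225, 493, 126, 1531, 393, 667, 2508, 136, 1002 and 429; and with the 7 libraries 4224, 4675, 4399, 6563, 4753, 5308, 7039, 3497, 5896 and 5880, where the spread comes from the WT and R9Q pairs alone. With the replicate block they were 3, 24, 0, 18, 2, 18, 218, 7, 31 and 0; the replicate numbers do not pair the samples, since deviations of replicates correlated between strains at -0.64 to 0.61, so fewer calls under the block do not mean weaker effects. With the 4 libraries of a contrast alone they were 4158, 820, 0, 0, 450, 0, 0, 0, 0 and 0. The stricter filter gave 58, 136, 21 and 27 for R9Q against WT, unc-16 against R9Q, T102I against WT and T102I against G265R, where fewer genes were tested, and genes with 1 transcript gave 140, 24 and 17 for unc-16 against R9Q, T102I against G265R and unc-16 against G265R. For the other shifts the cause was not tested.

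With 1 library left out the counts ranged over 0 to 97, 0 to 266, 0 to 13, 0 to 681, 0 to 1.0e+02 (rounded), 0 to 149, 7 to 1448, 0 to 70, 5 to 797 and 0 to 375. Without either R9Q replicate no gene was called in any main contrast by edgeR, and without unc-16 replicate 2 the main counts were 97, 266, 13 and 681. The 90 calls of named genes were followed under all alternatives except counts per transcript and genes with 1 transcript, and none changed direction; the stricter filter tested 85 of them and kept 85. All 90 remained with DESeq2, with the library set term, with no filter and with the 7 libraries, 88 with DESeq2 size factors, 84 with upper quartile factors, 50 with the block and 44 with the 4 libraries of a contrast. DESeq2, the set term, no filter and the 7 libraries each called more genes than the reported fit in every contrast. That they kept all 90 therefore says little about how firm these calls are. With 1 library left out 13 remained without R9Q replicate 1 or 2, 16 and 14 without WT replicates 1 and 2, 24 and 27 without T102I replicates 1 and 2, and 81 to 90 without a G265R or unc-16 library.

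unc-104 has 0 counts under every alternative, so no value can be given. unc-16 was called by edgeR with no filter in G265R against R9Q (-3.29), G265R against WT (-3.38) and unc-16 against G265R (2.93), and with the 7 libraries at -2.36, -2.44 and 2.71, and in T102I against G265R at 1.91. With 1 library left out its log2 fold change ranged over -0.40 to 0.32, -2.62 to -0.45, -8.05 to -2.34, -1.69 to 0.30, -2.70 to -0.53, -8.14 to -2.43, -1.78 to 0.22, 0.68 to 6.90, -0.54 to 2.22 and 1.62 to 7.72, in the order above.

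Called lists numbered 7, 7, 5, 9, 9, 7, 7, 6, 7 and 5 in the order above. With an estimated correlation they numbered 1 in unc-16 against WT and 0 in the other 9 contrasts. With fry they numbered 4, 3, 2, 4, 1 and 4 in R9Q against WT, T102I against R9Q, G265R against R9Q, T102I against WT, T102I against G265R and unc-16 against T102I, and within 1.5 times in the others. With 1 library left out they ranged over 7 to 8, 5 to 8, 5 to 7, 7 to 10, 7 to 11, 4 to 9, 7 to 9, 4 to 10, 4 to 10 and 5 to 10. Of the 28 list calls in the main contrasts, 0 remained with an estimated correlation, 11 with fry, 22 with the library set term, 22 with the 7 libraries and 28 with the block. The mitochondrial genome list turned upward in T102I (adjusted p = 0.784 with the set term, 0.302 with the 7 libraries) and in G265R (0.687 with the set term). For the mitochondrial genome list, R9Q_G265R against R9Q, the 7 libraries gave 0.00740, upward. In G265R without replicate 2, and with the 7 libraries, the list of molting genes turned downward (0.91 and 0.736), as did oocyte and eggshell genes (0.0156 and 0.0323) and histone genes (0.0291 and 0.0386). With any 1 library left out the adjusted p of these 3 lists in G265R ranged from 0.000133 to 0.91, 7.63e-05 to 0.446 and 7.63e-05 to 0.328.

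Genes of R9Q called the opposite way numbered 23, 0 and 1 in T102I, G265R and unc-16. At a threshold of 0.01 they were 3 in T102I and 0 in unc-16; with DESeq2 1.2e+02 (rounded), 40 and 60; with the set term 103, 28 and 53; with the 7 libraries 1900, 1277 and 1414; with the block 3 in T102I and 0 in unc-16; and with 1 library left out 0 to 62, 0 to 6 and 0 to 24. Genes shared by T102I and G265R, T102I and unc-16, and G265R and unc-16 numbered 0, 14 and 0; with the set term 80, 263 and 96; and with the 7 libraries 2263, 2477 and 2335. For T102I and unc-16 they were 4 with the block and 0 at a threshold of 0.01. Depth limits the lowest levels: 3 counts correspond to 0.419 to 0.481 CPM.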

Other observations

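No test in this part was chosen after its result was seen, apart from the choice of which planned list results to print. Measured against WT, the pals genes were higher as a set in all of the suppressed strains, with medians of 0.61 in T102I (camera adjusted p = 3.48e-06), 0.76 in G265R (0.000144) and 1.70 in unc-16 (6.2e-08). With an estimated correlation these gave adjusted p = 0.074, 0.129 and 0.0382. Over all genes tested 1, 2 and 6 pals genes rose, and 4, 6 and 12 adjusted over the list alone. Synaptic vesicle genes were lower as a set in T102I, 11 of 12 below 0 with a median of -0.45 (camera adjusted p = 0.0144; adjusted p = 0.289 with an estimated correlation). Medians were -0.41 in G265R and -0.67 in unc-16, not called (adjusted p = 0.121 and 0.0789). Body wall muscle markers were lower as a set in T102I, with a median of -0.55 (camera adjusted p = 0.00991, or 0.502 with an estimated correlation). Both T102I libraries also stood apart from WT in molting genes, with medians of 92.3 and 75.3 CPM against 1.21 and 1.24 CPM. The phase of the molting cycle at harvest was not separated from genotype in these lists.

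In the unc-16 strain, heat shock genes had a median of 6.32 against T102I (camera adjusted p = 1.61e-05; adjusted p = 0.305 with an estimated correlation) and 4.78 against G265R (4.41e-05; adjusted p = 0.347 with an estimated correlation). Neuropeptide genes in it were lower as a set, with medians of -0.58 against T102I (camera adjusted p = 0.00113; adjusted p = 0.417 with an estimated correlation) and -0.64 against G265R (7.97e-05; adjusted p = 0.347 with an estimated correlation). Germline genes were higher as a set, with medians of 0.57 and 0.62 (camera adjusted p = 0.00569 and 0.0127; adjusted p = 0.621 and 0.784 with an estimated correlation). Between T102I and G265R, fat metabolism genes had a median of 0.73 (camera adjusted p = 1.72e-05; adjusted p = 0.109 with an estimated correlation). Innate immunity genes had one of -1.60 (1.56e-06; adjusted p = 0.136 with an estimated correlation).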
